A study of Arabidopsis thaliana with 21 samples.

How the data were processed

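Rosettes of the Arabidopsis thaliana accession Col-0, grown on soil for 21 days at 22 °C with 16 h of light and 8 h of darkness, were sampled at the end of the night and after 2, 5 and 8 h of light. Per the labels' protocols, the light was either a standard intensity of 100 µE or a high intensity of 500 µE, set by the distance of the plants from the LED source. This gave 7 groups of 3 libraries each, 21 libraries in all: dark at 0 h, standard light at 2, 5 and 8 h, and high light at 2, 5 and 8 h. The series' design text states that tissue was harvested in biological triplicate. How many plants entered a sample is not given in the sources used here, so the p-values measure the spread between these samples. Groups and replicate numbers were taken from the sample titles, and the numbers were not used to pair samples.

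Per the labels' protocols, libraries were made from total RNA with a strand-specific kit that depletes plant ribosomal RNA and were sequenced as single-end reads of 75 bp on 1 NextSeq500 lane. The submitters' processing notes name FastQC 0.11.7, Trim Galore 0.4.4, Subread 1.5.0, SAMtools 1.3.1, featureCounts and edgeR. Per the file headers, the deposited counts were made with featureCounts in reverse-stranded mode, with chimeric fragments not counted, over 1 span per gene from its start to its end, so that reads in introns entered the count of their gene. The aligner settings and the genome build are not given in the sources used here. The counts are raw whole numbers, 1 file per library, and hold 33341 loci. Every locus has a name, and no line of unassigned reads was among them.

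The authors also deposited a table of log2 RPKM per library for part of the loci, whose filter, prior count and scaling factors are not given in the sources used here. That table was not used here. A further table deposited by the authors holds their own comparisons, with a log2 fold change, an average log2 CPM and an adjusted p-value (FDR) for each gene that passed an FDR of 0.05 in the glmTreat test of edgeR. The minimum fold of that test is not stated. Its calls are set beside those computed here from the deposited counts.

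Gene symbols, gene types and coordinates came from the TAIR10.1 annotation. Of the 33341 loci, 32909 matched by locus tag, 32908 of them with the same start and end, 123 organelle loci were matched by position, and 309 were left without a match. A symbol was given for 10780 loci, and other genes are named by their locus tag. Coordinates are 1-based on TAIR10.1. Reads from near-identical copies cannot be assigned with certainty, so values for members of the LHCB1, LHCB2, RBCS, ELIP, IGMT, BIP and HSC70 families, and for ribosomal protein genes with several copies, are uncertain as to the copy. Counting used the strand, so overlapping genes on opposite strands were told apart.

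Total counts per library ran from 6545003 to 31449700 with a median of 13592728. A floor of 3 counts in 1 library corresponded to 0.106 to 0.454 CPM. Where all libraries of a group held no count for a gene, the fold is given only as a bound against that floor per library, and where a group held 1 to 3 counts the ratio is given with a 95% Poisson interval. Both cover counting error only, since PCR copies were not identified.

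Counts were normalised with TMM and tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16 (robust dispersion, 1 coefficient per group, all 21 libraries in the fit). The filter filterByExpr left 19626 loci. P-values were adjusted by the Benjamini-Hochberg method over these loci, separately for each contrast, and a gene is said to have risen or fallen where the adjusted p was under 0.05. Log2 fold changes are given ± SE, with the SE computed as the absolute log2 fold change over the square root of F, and levels are mean CPM ± SD over 3 libraries, with TMM-scaled library sizes. Fitted fold changes used the default prior count of edgeR, and log2 CPM per library a prior count of 2. The contrasts were high against standard light at 2, 5 and 8 h, each light group against dark, the high-light effect averaged over the 3 times, and the difference of the high-light effect at 8 h and at 2 h.

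Before the data were examined, 23 gene lists were fixed: photoprotection, antioxidant enzymes, stress transcription factors and early stress genes, heat shock proteins, chloroplast proteases and photosystem II repair, light-harvesting antenna, nuclear photosystem subunits, chloroplast-encoded photosynthesis genes, chloroplast-encoded gene expression genes, Calvin-Benson cycle, photorespiration, thiamine biosynthesis, chlorophyll biosynthesis, flavonoid and anthocyanin synthesis, circadian clock, darkness and carbon starvation, starch and sugar metabolism, light signalling, cold, drought and abscisic acid response, endoplasmic reticulum chaperones, proteasome, jasmonate and salicylate defence, and nuclear-encoded ribosomal proteins. Markers of root, guard cells, vascular tissue, epidermis and trichomes, dividing cells, flower, seed and senescing leaf were fixed likewise. A list was tested where at least 5 members were measured, with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, and adjusted over the 23 lists of a contrast. The same test with a correlation estimated from the data was an alternative. Counts of list members are given over all loci tested and also adjusted over the list alone.

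The genes named were chosen by a rule fixed before the data were examined. It takes 14 genes known from work on light, cold and starvation in every comparison of high with standard light (ELIP1, ELIP2, APX2, TT4, PAP1, HSP101, HSP21, GPT2, RCA, THI1, LHCB2.4, CCA1, ASN1 and PSBA). For each such comparison it adds the 8 largest positive and 8 largest negative log2 fold changes among protein-coding genes with a symbol, an adjusted p under 0.05, a higher group of at least 10 CPM and libraries that did not overlap, which chance alone gives for 10% of genes. For the other contrasts it adds 5 and 5, without the condition on overlap for the mean and the difference. From each list it takes up to 4 members with the smallest adjusted p in each contrast and the members with the largest change. From these members, mainly those that kept their call without each single library are printed. List members given in brackets after a count of 5 or fewer were chosen after their values were seen, and of 529 such calls over every list and contrast 305 held without each single library. For 1 of these counts the members are not reported here.

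Alternatives fixed in advance were size factors of the DESeq2 kind (RLE), no filter beyond 1 count, a filter of 5 CPM in 3 samples, nuclear genes only, the replicate number as a block, glmTreat against a fold of 1.5, DESeq2 1.42.0 in place of edgeR, only the compared groups in the fit, an estimated correlation in camera, another denominator for the chloroplast share of the counts, and leaving out each library in turn. Those added after the data were seen were the log2 share of ribosomal RNA in the counts as a covariate, limma voom with sample quality weights, leaving out both libraries that stand apart (the 5 h high light library with the highest ribosomal RNA share and the 2 h standard light library with the fewest counts), and the mean over 2 and 8 h only. The tests were tried on simulated counts of 19626 loci with 200 changed genes, drawn from the means and library sizes of these data. For high against standard light at 2 h edgeR recovered 2.99% of the genes changed 1.5-fold, 23.9% of those changed 2-fold and 71.2% of those changed 4-fold, with 8.33% of its calls false, at 5 h 2.99%, 26.9% and 81.8% with 1.3% false, and at 8 h 1.49%, 23.9% and 77.3% with 4.23% false. Whether these shares hold for the real libraries was not tested. Other computations used Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and plots matplotlib 3.10.9.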

Results

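RNA sequencing of rosettes was available for 21 Arabidopsis libraries, 3 in each of 7 groups. Plants were sampled in darkness at the end of the night (T0D), after 2, 5 and 8 h of standard light at 100 µE (T2L, T5L, T8L), and after 2, 5 and 8 h of high light at 500 µE (T2H, T5H, T8H). The series' title concerns enzymes degraded under high light and their transcripts. Total counts per library were 13592728 to 15536916 in T0D, 6545003 to 15332727 in T2L, 12778575 to 16229322 in T5L and 12631925 to 14257715 in T8L. They were 11515249 to 13265746 in T2H, 9852801 to 16459582 in T5H and 9257546 to 31449700 in T8H. Replicates of every group differed by more than sampling noise, so each library was counted as 1 sample.

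Ribosomal RNA took 0.0423% of the counts in T5H replicate 2 and 32.9% in T5H replicate 3. Its mean share was 3% ± 3.54 in T0D, 11.6% ± 6.44 in T2L, 3.15% ± 1.27 in T5L and 5.38% ± 2.75 in T8L (SD, n = 3). In high light it was 1.78% ± 2.77 in T2H, 11% ± 18.9 in T5H and 23% ± 3.59 in T8H. Chloroplast genes held 39.5% ± 4.06 of the counts in T0D, 41.8% ± 7.76 in T2L, 48.9% ± 1.31 in T5L and 48.7% ± 2.03 in T8L. In high light they held 39.9% ± 4.99, 28.7% ± 4.09 and 36.8% ± 2.14 at 2, 5 and 8 h. Over protein-coding loci alone the share was 51% ± 0.716 in T8L and 46.9% ± 1.19 in T8H, and 49.9% ± 1.49 in T5L and 32.9% ± 12.9 in T5H (22.8, 28.6 and 47.5% in replicates 1, 2 and 3). Within groups, the mean log2 level of chloroplast-encoded gene expression genes changed by 0.09 ± 0.02 per doubling of the ribosomal RNA share, and that of antenna genes by -0.09 ± 0.02.

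**Figure D1:**
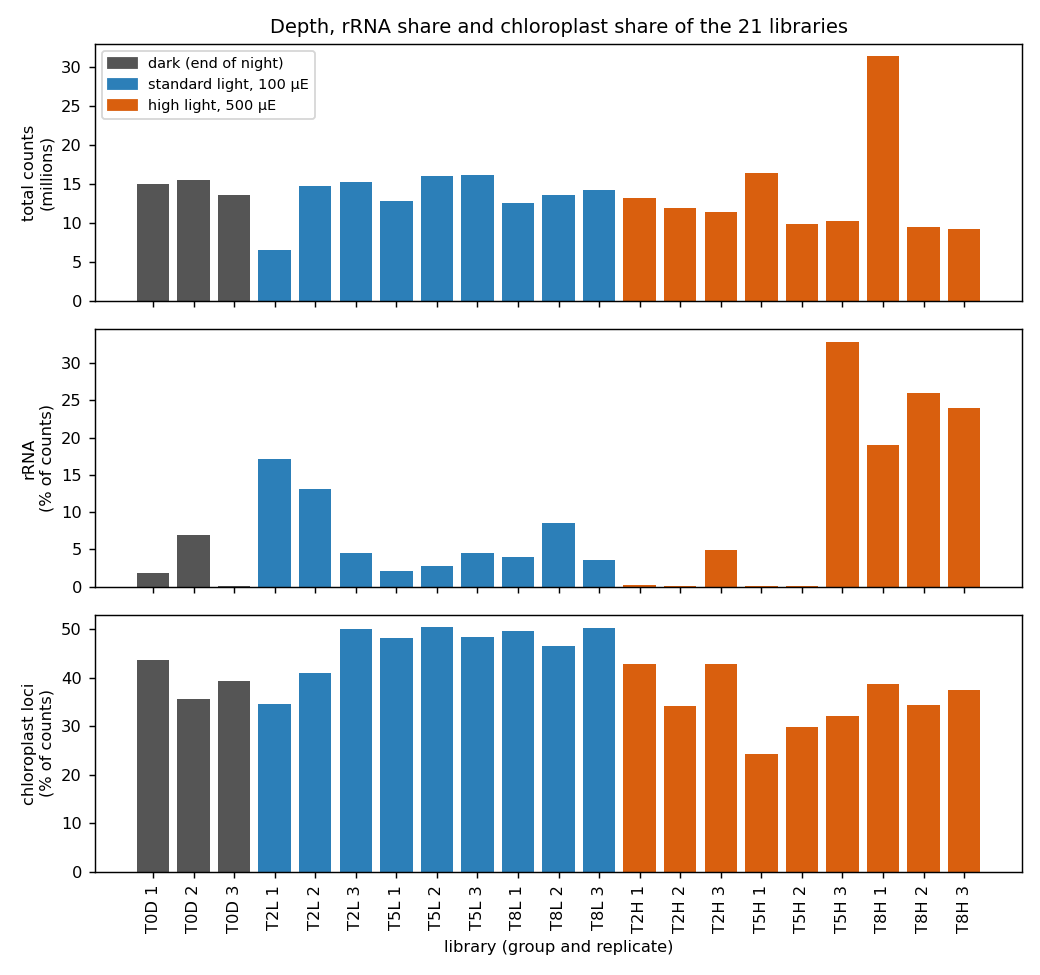
Total counts, ribosomal RNA share and chloroplast share of the counts in each of the 21 libraries by group. T2L replicate 1 has the fewest counts (6545003) and T5H replicate 3 the highest ribosomal RNA share (32.9%).

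High light was compared with standard light after 2 h to see which transcripts differed early in the day. HSP70 (AT3G12580, chromosome 3, 3991117 to 3993886), a cytosolic chaperone gene, rose from 1.33 ± 0.551 to 19.3 ± 6.56 CPM (log2 fold change 3.91 ± 0.58, adjusted p = 0.0013). Its relative Hsp70-2 rose from 20.4 to 88.9 CPM (2.11 ± 0.35, adjusted p = 0.00371). FER1 (AT5G01600, chromosome 5, 227953 to 230051), for a plastid ferritin, rose from 67 ± 8.94 to 522 ± 146 CPM (2.96 ± 0.29, adjusted p = 4.98e-06). The protease inhibitor gene KTI1 rose from 0.207 to 11.3 CPM (5.46 ± 0.91, adjusted p = 0.00377), and the alcohol dehydrogenase gene ELI3-2 from 3.85 to 24.2 CPM (2.62 ± 0.43, adjusted p = 0.0026). RVE1 (AT5G17300, chromosome 5, 5690225 to 5692992), a clock-regulated transcription factor, fell from 28.4 ± 9.02 to 4.77 ± 1.33 CPM (-2.56 ± 0.29, adjusted p = 4.71e-05). TPS8, of the trehalose phosphate synthase family, fell from 27.1 to 5.51 CPM (-2.28 ± 0.34, adjusted p = 0.00107). IGMT4, an indole glucosinolate methyltransferase gene uncertain among its copies, fell from 82.6 to 15.3 CPM, and FRO6, a leaf ferric reductase gene, from 93.9 to 26.9 CPM. The bZIP factor gene BZO2H3 changed by -1.91 ± 0.34, the ethylene response factor gene ERF2 by -2.69 ± 0.50 and the flowering repressor gene CDF2 by -1.75 ± 0.33. With the ribosomal RNA share as covariate, the adjusted p was 0.0853 for ERF2 and 0.0724 for CDF2. With limma voom it was 0.229 for HSP70, 0.0705 for Hsp70-2, 0.125 for KTI1 and 0.117 for ERF2.

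Of 23 heat shock genes measured at 2 h, 6 rose and 17 did not pass (7 adjusted over the list alone). Heat shock genes had a median log2 change of 0.76 (camera adjusted p = 4.88e-08, or 0.188 with an estimated correlation). HSFA2, a heat shock factor gene, rose from 0.138 to 4.42 CPM (4.67 ± 0.71, adjusted p = 0.001). HSFA2 and HSP70 alone of the 6 passed with the ribosomal RNA share as covariate, where HSC70-1 had an adjusted p of 0.0548 and ROF2 0.0835. HSC70-1 also had 0.0726 without T2L replicate 1, and ROF2 0.213 with limma voom. Of 29 antioxidant enzyme genes measured at 2 h, 3 rose (APX1, FSD1 and VTC2) and 26 did not pass (4 adjusted over the list alone). Antioxidant enzyme genes had a median log2 change of 0.36 (camera adjusted p = 0.000411, or 0.419 with an estimated correlation). Antioxidant enzyme genes had an adjusted p of 0.0662 with the ribosomal RNA share as covariate. APX1, for the main cytosolic ascorbate peroxidase, rose from 91.8 to 278 CPM (1.60 ± 0.20, adjusted p = 0.000143). Of 33 chloroplast protease genes measured at 2 h, 4 rose (FTSH1, FTSH8, CLPD and SPPA) and 29 did not pass (5 adjusted over the list alone). Chloroplast protease genes had a median log2 change of 0.08 (camera adjusted p = 0.0512). FTSH8 (1.36 ± 0.19) and SPPA (0.85 ± 0.16), for thylakoid proteases, were among them. Of 22 photoprotection genes measured at 2 h, 2 rose (ELIP2 and BCH1), 1 fell (NPQ1) and 19 did not pass (4 and 3 adjusted over the list alone). Photoprotection genes had a median log2 change of 0.12 (camera adjusted p = 0.169). BCH1, a carotene hydroxylase gene of the xanthophyll pathway, rose by 1.29 ± 0.20, adjusted p = 0.00107. With the covariate the adjusted p was 0.294 for FSD1, 0.152 for VTC2, 0.248 for CLPD and 0.0943 for NPQ1, and with limma voom 0.143, 0.0508 and 0.0711 for FSD1, VTC2 and CLPD. Without 1 library it reached 0.179 for FSD1 (T2H replicate 2) and VTC2 (T2L replicate 1), 0.196 for CLPD (T2H replicate 1), and 0.133 for NPQ1 and 0.083 for ELIP2 (T2L replicate 1). With only the groups compared in the fit SPPA had 0.0644, and FSD1, VTC2, CLPD and NPQ1 did not pass.

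At 2 h the ribosomal RNA share was 1.78% in T2H and 11.6% in T2L. Of 26 chloroplast-encoded gene expression genes measured at 2 h, 4 fell (RPOC2, RPOC1, RPOB and RPL16) and 22 did not pass (20 adjusted over the list alone). Chloroplast-encoded gene expression genes had a median log2 change of -0.82 (camera adjusted p = 3.5e-13, or 0.275 with an estimated correlation). RPOB, for a subunit of the plastid RNA polymerase, changed by -0.81 ± 0.19, adjusted p = 0.0202. The adjusted p for RPOB was 0.0858 without T2L replicate 1, 0.108 without T2H replicate 1 and 0.0908 without T2H replicate 2. Of 43 chloroplast-encoded photosynthesis genes measured at 2 h, 3 fell (NDHF, NDHG and NDHA) and 40 did not pass (10 adjusted over the list alone). Chloroplast-encoded photosynthesis genes had a median log2 change of -0.52 (camera adjusted p = 7.73e-08, or 0.636 with an estimated correlation). PSBA, for the D1 protein of photosystem II, did not pass (-0.15 ± 0.40, adjusted p = 0.891). With the covariate the 7 members in brackets did not pass, with adjusted p from 0.0802 for RPOB to 0.25 for NDHF. With limma voom RPOC2 (0.0567) and NDHF (0.0655) did not pass. The other 6 were also lost without 1 library, with adjusted p up to 0.205 for RPOC2, 0.127 for RPOC1, 0.181 for NDHG and 0.148 for NDHA without T2H replicate 2, and 0.213 for RPL16 and 0.19 for NDHF without T2L replicate 1.

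Of 22 nuclear photosystem genes measured at 2 h, edgeR called 0, with 8 at an unadjusted p under 0.05, DESeq2 0 and limma voom 0 (0 adjusted over the list alone). Nuclear photosystem genes had a median log2 change of 0.34 (camera adjusted p = 0.000411, or 0.636 with an estimated correlation). Nuclear photosystem genes had an adjusted p of 0.706 with the ribosomal RNA share as covariate. Of 53 ribosomal protein genes measured at 2 h, 3 rose and 50 did not pass (as many adjusted over the list alone). Ribosomal protein genes had a median log2 change of 0.23 (camera adjusted p = 0.000294, or 0.636 with an estimated correlation). Ribosomal protein genes had an adjusted p of 0.084 with the ribosomal RNA share as covariate and 0.0835 without T2L replicate 1. RPSAb rose by 1.48 ± 0.27, adjusted p = 0.00487, or 0.061 with only the groups compared in the fit. Of 20 proteasome genes measured at 2 h, edgeR called 0, with 4 at an unadjusted p under 0.05, DESeq2 1 and limma voom 1 (0 adjusted over the list alone). Proteasome genes had a median log2 change of 0.22 (camera adjusted p = 0.0194, or 0.636 with an estimated correlation). Proteasome genes had an adjusted p of 0.345 with the ribosomal RNA share as covariate, 0.217 with both libraries that stand apart left out, 0.267 without T2L replicate 1, 0.053 without T2L replicate 2 and 0.0753 without T2H replicate 1. Of 20 clock genes measured at 2 h, 1 fell (RVE1) and 19 did not pass (2 and 5 adjusted over the list alone). Clock genes had a median log2 change of -0.31 (camera adjusted p = 0.00243, or 0.0615 with an estimated correlation). Of 20 starvation genes measured at 2 h, 1 rose (BGLU30), 2 fell (TPS8 and TPS9) and 17 did not pass (1 and 4 adjusted over the list alone). Starvation genes had a median log2 change of -0.16 (camera adjusted p = 0.0147, or 0.445 with an estimated correlation). Starvation genes had an adjusted p of 0.0623 with the ribosomal RNA share as covariate and 0.326 without T2H replicate 2. TPS9 had 0.058 with that covariate and 0.0753 without T2L replicate 2, and BGLU30 0.22 with limma voom and 0.0858 without T2L replicate 1. Of 21 cold and abscisic acid genes measured at 2 h, 1 rose (GOLS2) and 20 did not pass (as many adjusted over the list alone). Cold and abscisic acid genes had a median log2 change of 0.88 (camera adjusted p = 0.000411, or 0.636 with an estimated correlation). Cold and abscisic acid genes had an adjusted p of 0.0694 without T2L replicate 3 and 0.186 without T2H replicate 1. Camera did not call the other lists, with adjusted p = 0.126 for starch and sugar, 0.549 for light signalling, 0.229 for flavonoids, 0.549 for stress factors and 0.146 for the antenna. It gave 0.126 for the Calvin-Benson cycle, 0.733 for photorespiration, 0.265 for reticulum chaperones and 0.135 for defence. Thiamine synthesis had a median of -0.11 and a mean of 0.05 (adjusted p = 0.733), and chlorophyll synthesis a median of 0.14 and a mean of -0.02 (adjusted p = 0.479).

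ELIP2, an early light-induced thylakoid protein gene with a close copy, rose at 2 h from 27.1 ± 12.3 to 243 ± 106 CPM (3.15 ± 0.62, adjusted p = 0.017). Its adjusted p was 0.083 without T2L replicate 1, 0.05 without T2L replicate 2 and 0.0564 without T2H replicate 1. ELIP1 went from 55 to 256 CPM without passing (2.21 ± 0.59, adjusted p = 0.0607). The chaperone gene HSP101 rose by 1.42 ± 0.35, adjusted p = 0.027, with an adjusted p of 0.131 without T2L replicate 1, 0.054 without T2L replicate 2, 0.0607 without T2H replicate 1 and 0.129 without T2H replicate 2. GPT2, for a glucose phosphate translocator, rose by 1.59 ± 0.41, adjusted p = 0.0447. For GPT2 the adjusted p was 0.131 without T2L replicate 1, 0.139 without T2L replicate 2, 0.066 without T2L replicate 3, 0.144 without T2H replicate 1, 0.0647 without T2H replicate 2 and 0.073 without T2H replicate 3. HSP90.1 rose by 2.61 ± 0.51, adjusted p = 0.0133, with an adjusted p of 0.0545 without T2L replicate 1. GOLS2, for galactinol synthase, rose by 1.94 ± 0.52, adjusted p = 0.0488, with an adjusted p of 0.19 without T2L replicate 1, 0.115 without T2L replicate 3, 0.212 without T2H replicate 1 and 0.0538 without T2H replicate 2. RAV2 changed by -2.19 ± 0.50, adjusted p = 0.0233, with an adjusted p of 0.108 without T2L replicate 1, 0.0522 without T2H replicate 1 and 0.0985 without T2H replicate 2. TT4, PAP1, RCA, THI1, LHCB2.4, CCA1 and ASN1 did not pass, with adjusted p = 0.592, 0.703, 0.696, 0.346, 0.32, 0.233 and 0.562. With the covariate the adjusted p of ELIP2, HSP101, GPT2, HSP90.1, GOLS2 and RAV2 was 0.0897, 0.21, 0.145, 0.0912, 0.145 and 0.0917. With limma voom that of the last 5 was 0.158, 0.106, 0.264, 0.329 and 0.206. APX2 and HSP21 held 5 and 2 counts over all libraries and were not tested.

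Of 19626 genes tested at 2 h, 284 rose and 239 fell, 162 and 140 of them by at least 2-fold. The 523 calls became 110 without T2L replicate 1, 293 without T2L replicate 2, 791 without T2L replicate 3, 154 without T2H replicate 1, 223 without T2H replicate 2 and 164 with the ribosomal RNA share as covariate. With only the groups compared in the fit they became 163, without HSP101, GOLS2, TPS9, NDHA, RPOB, RPOC1, RPOC2 and RPL16. Camera called 10 lists, up to 12 for other splits of these 6 libraries, and 0 with an estimated correlation.

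**Figure D2:**
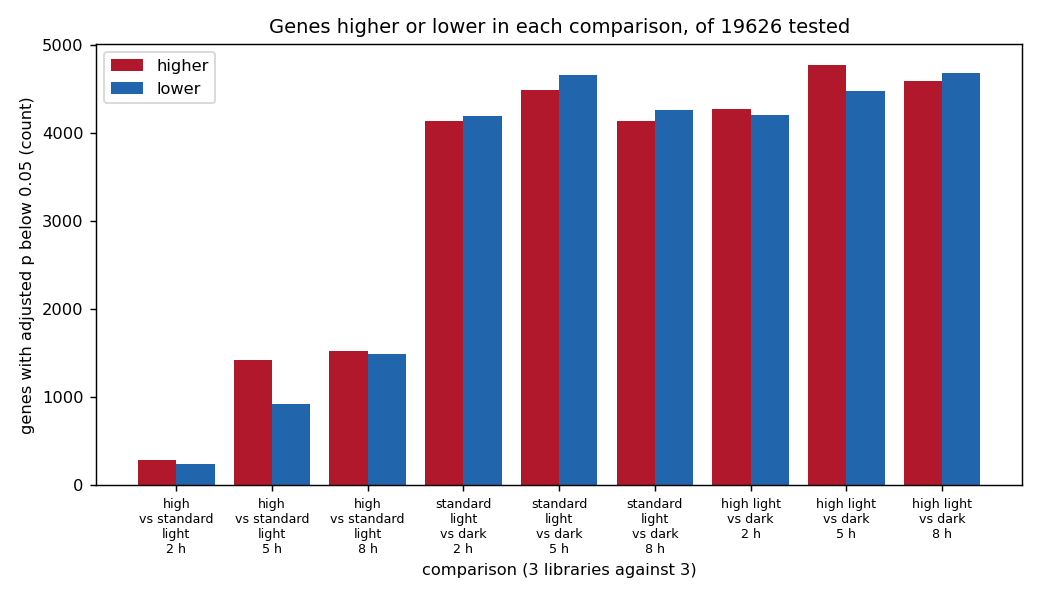
Number of genes that rose or fell in each comparison of high with standard light and of each light group with dark, among 19626 tested genes (edgeR, adjusted p under 0.05). High light differed from standard light in 523, 2361 and 3025 genes at 2, 5 and 8 h, and each light group differed from dark in 8331 to 9275 genes.

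High light was next compared with standard light after 5 h. UF3GT (AT5G54060, chromosome 5, 21936746 to 21938396), for an anthocyanin glycosyltransferase, rose from 1.97 ± 0.847 to 23.8 ± 14.4 CPM (log2 fold change 3.56 ± 0.60, adjusted p = 0.00132). TT7, for flavonoid 3'-hydroxylase, rose from 1.1 to 13 CPM (3.55 ± 0.72, adjusted p = 0.00482). ELIP1 (AT3G22840, chromosome 3, 8084405 to 8085669) rose from 2.52 ± 0.596 to 37.6 ± 22.8 CPM (3.89 ± 0.69, adjusted p = 0.00232), and ELIP2 by 3.01 ± 0.65, adjusted p = 0.00779, with an adjusted p of 0.064 without T5H replicate 1. With limma voom the adjusted p was 0.0632 for TT7 and 0.105 for ELIP2. NEET, for an iron-sulphur protein, rose from 4.7 to 44.6 CPM, and the ammonium transporter gene AMT1;2 from 1.66 to 12.2 CPM. HAI1, a phosphatase gene of abscisic acid signalling, rose from 0.893 to 10.7 CPM, and the mannan synthase gene CSLA01 from 1.77 to 20.8 CPM. ASN1 (AT3G47340, chromosome 3, 17437840 to 17441431), the dark-induced asparagine synthetase gene, fell from 10.6 ± 5.48 to 1.89 ± 0.423 CPM (-2.53 ± 0.50, adjusted p = 0.00336). TPS8 fell from 15.7 to 1.73 CPM and TPS11 from 15.3 to 3.21 CPM. TRM3 fell from 37.3 to 6.03 CPM, BBX17 from 10.4 to 1.05 CPM (adjusted p = 0.0525 with only the groups compared in the fit) and the kinase gene CIPK21 from 100 to 19.9 CPM. GOLS3 changed by -2.35 ± 0.56, adjusted p = 0.0122, with an adjusted p of 0.0516 without T5L replicate 2, 0.0609 without T5H replicate 1 and 0.0527 without T5H replicate 2. SCPL13 changed by -2.91 ± 0.83, adjusted p = 0.0301. For SCPL13 the adjusted p was 0.101 without T5L replicate 1, 0.061 without T5L replicate 2, 0.0631 without T5L replicate 3, 0.0722 without T5H replicate 1 and 0.118 without T5H replicate 2.

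Of 27 flavonoid genes measured at 5 h, 21 rose and 6 did not pass (24 adjusted over the list alone). Flavonoid genes had a median log2 change of 2.39 (camera adjusted p = 1.56e-20, or 0.0458 with an estimated correlation). TT4 (AT5G13930, chromosome 5, 4488476 to 4490264), the chalcone synthase gene, rose from 44.4 ± 4.94 to 271 ± 208 CPM (2.61 ± 0.52, adjusted p = 0.00384), and MYB111, a flavonol regulator, by 2.67 ± 0.40. Of 22 light-signalling genes measured at 5 h, 8 rose, 3 fell (PHYA, CRY1 and CRY2) and 11 did not pass (11 and 7 adjusted over the list alone). Light-signalling genes had a median log2 change of 0.31 (camera adjusted p = 0.000906, or 0.0375 with an estimated correlation). HY5 (AT5G11260, chromosome 5, 3593335 to 3595073), a central factor of light responses, rose from 2.08 to 12.6 CPM (2.58 ± 0.28, adjusted p = 2.61e-06), and RUP2, which represses UV-B signalling, by 3.87 ± 0.39. The photoreceptor gene CRY2 was among those that fell (-1.0 ± 0.16). PHYA had an adjusted p of 0.1 with no filter and up to 0.121 without 1 library (T5L replicate 1). Of 20 starvation genes measured at 5 h, 7 fell and 13 did not pass (8 adjusted over the list alone). Starvation genes had a median log2 change of -0.60 (camera adjusted p = 1.7e-06, or 0.0458 with an estimated correlation). SEN1 changed by -3.52 ± 0.65 and the autophagy gene ATG8E by -1.71 ± 0.31.

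Of 21 Calvin-Benson cycle genes measured at 5 h, 12 rose and 9 did not pass (16 adjusted over the list alone). Calvin-Benson cycle genes had a median log2 change of 0.80 (camera adjusted p = 7.98e-07, or 0.267 with an estimated correlation). CP12-2, for a regulator of the cycle, rose by 1.63 ± 0.24. Of 17 photorespiration genes measured at 5 h, 9 rose and 8 did not pass (11 and 1 adjusted over the list alone). Photorespiration genes had a median log2 change of 0.61 (camera adjusted p = 0.000155, or 0.267 with an estimated correlation). GLDP1, for the glycine decarboxylase P protein, rose by 1.25 ± 0.24. With only the groups compared in the fit the adjusted p was 0.0783 for GLDP1, 0.0594 for CPHSC70-1 and 0.0545 for RPL24A, and HSC70-1 and CLPB3 did not pass. Of 22 photoprotection genes measured at 5 h, 9 rose and 13 did not pass (as many adjusted over the list alone). Photoprotection genes had a median log2 change of 0.19 (camera adjusted p = 0.000309, or 0.152 with an estimated correlation). NPQ4, for PsbS, rose from 302 to 787 CPM (1.38 ± 0.23, adjusted p = 0.000369). Of 29 antioxidant enzyme genes measured at 5 h, 9 rose, 2 fell (GPX1 and GSH2) and 18 did not pass (11 and 2 adjusted over the list alone). Antioxidant enzyme genes had a median log2 change of 0.31 (camera adjusted p = 0.000906, or 0.267 with an estimated correlation). GPX1, a glutathione peroxidase gene, was among those that fell (-1.22 ± 0.19). Of 23 heat shock genes measured at 5 h, 5 rose (HSP17.6II, HSC70-1, CLPB3, CPHSC70-1 and CPHSC70-2) and 18 did not pass (8 adjusted over the list alone). Heat shock genes had a median log2 change of 0.64 (camera adjusted p = 0.000975, or 0.267 with an estimated correlation). CPHSC70-2 of the chloroplast rose by 1.10 ± 0.22. With the covariate the adjusted p was 0.0806 for HSP17.6II, 0.0646 for HSC70-1 and 0.0512 for CLPB3, and without 1 library up to 0.141 (T5L replicate 2), 0.252 and 0.211 (T5H replicate 1). Of 11 reticulum chaperone genes measured at 5 h, 8 rose and 3 did not pass (10 adjusted over the list alone). Reticulum chaperone genes had a median log2 change of 0.95 (camera adjusted p = 8.77e-07, or 0.215 with an estimated correlation). CNX1 rose from 119 to 376 CPM. Of 53 ribosomal protein genes measured at 5 h, 20 rose and 33 did not pass (29 adjusted over the list alone). Ribosomal protein genes had a median log2 change of 0.54 (camera adjusted p = 5.37e-10, or 0.208 with an estimated correlation). RPL24A rose from 90 to 205 CPM.

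Of 26 chloroplast-encoded gene expression genes measured at 5 h, 10 fell and 16 did not pass (16 adjusted over the list alone). Chloroplast-encoded gene expression genes had a median log2 change of -0.71 (camera adjusted p = 2.8e-09, or 0.244 with an estimated correlation). RPS19 changed by -1.02 ± 0.22 and RPOA by -0.92 ± 0.21. Of 43 chloroplast-encoded photosynthesis genes measured at 5 h, 6 fell and 37 did not pass (14 adjusted over the list alone). Chloroplast-encoded photosynthesis genes had a median log2 change of -0.43 (camera adjusted p = 1.66e-05, or 0.503 with an estimated correlation). PSBA (ATCG00020, the chloroplast chromosome, 383 to 1444) went from 182000 ± 18400 to 81600 ± 62000 CPM without passing (-1.16 ± 0.40, adjusted p = 0.0606). Of 20 antenna genes measured at 5 h, 1 rose (LHCB4.3), 5 fell (LHCA4, LHCB1.4, LHCB2.2, LHCB2.4 and LHCB4.2) and 14 did not pass (2 and 6 adjusted over the list alone). Antenna genes had a median log2 change of -0.20 (camera adjusted p = 0.00846, or 0.6 with an estimated correlation). Antenna genes had an adjusted p of 0.714 with both libraries that stand apart left out and 0.678 without T5H replicate 3. LHCB2.4 fell from 186 to 52.9 CPM (-1.81 ± 0.29, adjusted p = 0.000299). LHCB4.3 had an adjusted p of 0.0542 without T5L replicate 2, 0.0758 without T5H replicate 1 and 0.082 without T5H replicate 2, and LHCA4 up to 0.0728 without T5L replicate 3. With only the groups compared in the fit the adjusted p was 0.0952 for RPS19, 0.0911 for RPOA, 0.0808 for LHCB1.4, 0.064 for LHCB2.2, 0.0716 for LHCB4.2 and 0.0556 for LHCB4.3. The ribosomal RNA share was 32.9% in T5H replicate 3 and under 0.1% in the other 2 libraries of T5H.

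Camera gave adjusted p = 0.132 at 5 h for stress factors, where ZAT10 (1.93 ± 0.30) and ZAT12 (1.74 ± 0.36) rose. The value was 0.205 for chlorophyll synthesis, where PORB fell from 590 to 271 CPM (adjusted p = 0.0601 with only the groups compared in the fit), 0.0645 for chloroplast proteases and 0.105 for starch genes. It was 0.458 for the clock, where LHY fell from 20.1 to 6.22 CPM, 0.413 for cold genes, 0.29 for the proteasome and 0.183 for defence. Nuclear photosystem genes had a median of 0.09 and a mean of -0.01 (adjusted p = 0.533), and thiamine synthesis genes a median and mean below 0 with the test pointing up (adjusted p = 0.932). GPT2 rose at 5 h from 15.2 to 71.3 CPM (2.23 ± 0.40, adjusted p = 0.00143). RCA, for Rubisco activase, rose by 0.90 ± 0.26, adjusted p = 0.0252. The adjusted p for RCA was 0.0716 without T5L replicate 1, 0.0956 without T5L replicate 2, 0.0809 without T5L replicate 3, 0.198 without T5H replicate 1 and 0.108 without T5H replicate 2, and 0.08 with the ribosomal RNA share as covariate. THI1, for thiazole synthase, rose by 0.76 ± 0.22, adjusted p = 0.0224, with an adjusted p of 0.0769 without T5L replicate 1, 0.104 without T5L replicate 2, 0.0502 without T5L replicate 3, 0.154 without T5H replicate 1 and 0.0788 without T5H replicate 2. With only the groups compared in the fit RCA had 0.21, THI1 0.172 and SCPL13 0.143. PAP1, HSP101 and CCA1 did not pass, with adjusted p = 0.0883, 0.7 and 0.813.

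At 5 h 1431 genes rose and 930 fell, 676 and 500 of them by at least 2-fold. The 2361 calls became 1097 without T5L replicate 1, 1277 without T5L replicate 2, 1244 without T5L replicate 3, 847 without T5H replicate 1, 1550 without T5H replicate 2 and 4678 without T5H replicate 3. Camera called 13 lists, and up to 14 for other splits of these 6 libraries.

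**Figure D3:**
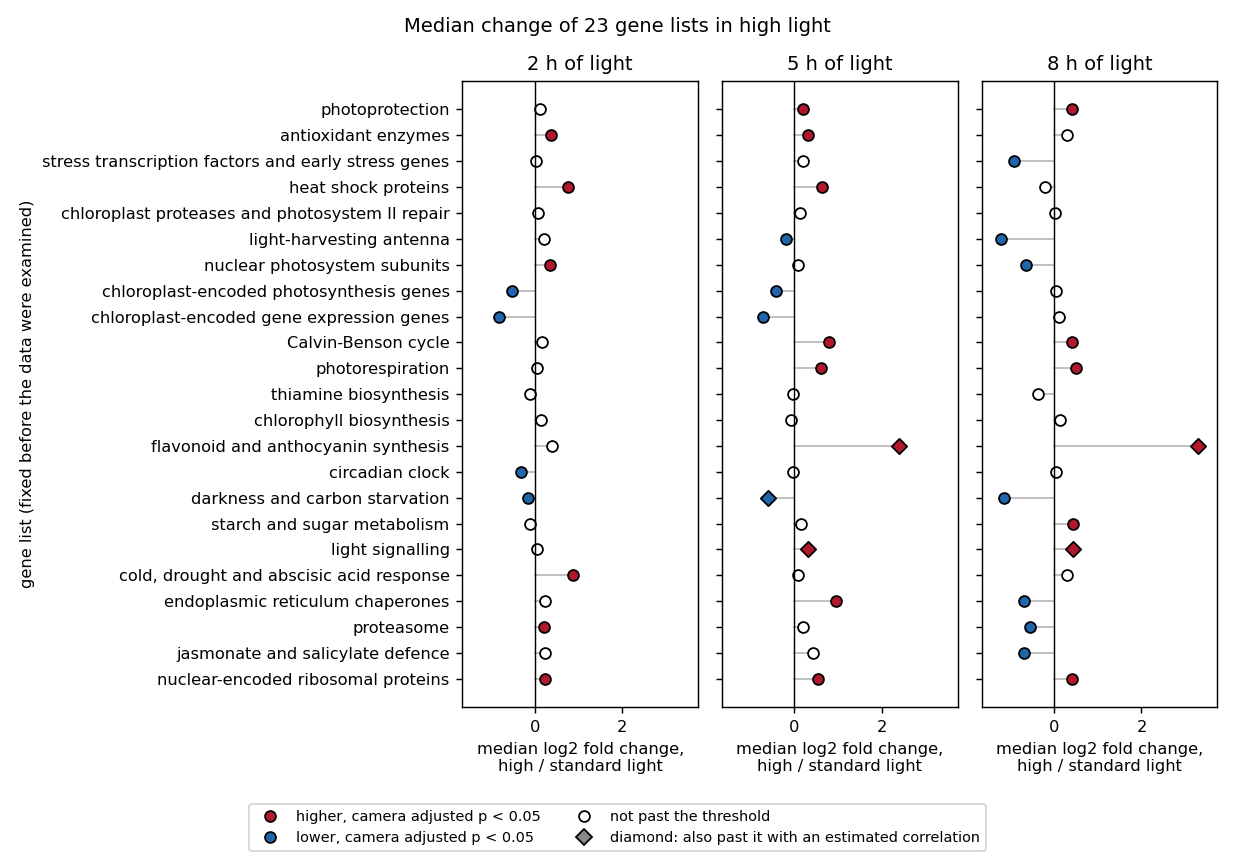
Median log2 fold change of each of the 23 gene lists in high against standard light at 2, 5 and 8 h. The flavonoid and anthocyanin list has medians of 2.39 at 5 h and 3.29 at 8 h, and the light-harvesting antenna list -1.21 at 8 h.

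At 8 h high was compared with standard light. UF3GT rose from 1.42 ± 1.3 to 51.2 ± 28.7 CPM (log2 fold change 5.14 ± 0.63, adjusted p = 6.05e-05). DFR (AT5G42800, chromosome 5, 17164093 to 17166032), for dihydroflavonol reductase, rose from 2.63 ± 1.81 to 67.7 ± 47.4 CPM (4.67 ± 0.60, adjusted p = 9.07e-05). LDOX, for anthocyanidin synthase, rose from 4.6 to 70.7 CPM, F3H from 1.27 to 24.5 CPM and TT4 from 3.73 to 55.8 CPM. MYB111 rose from 0.854 to 13.7 CPM, TT7 by 4.13 ± 0.76 and CSLA01 by 4.35 ± 0.82. LHCB1.4 (AT2G34430, chromosome 2, 14524607 to 14525918), an antenna gene with close copies, fell from 461 ± 132 to 61.8 ± 23 CPM (-2.90 ± 0.30, adjusted p = 2.15e-06). UGT76B1 (AT3G11340, chromosome 3, 3556554 to 3558361), for a glucosyltransferase acting on defence signals, fell from 34.1 ± 22.2 to 1.63 ± 0.999 CPM (-4.48 ± 0.60, adjusted p = 4.4e-05). ALD1, of pipecolic acid synthesis, fell from 21.4 to 2.75 CPM, and ARD3, of the methionine cycle, from 54.4 to 6.17 CPM. BCB changed by -2.62 ± 0.41, 4CL5 by -2.80 ± 0.49 (adjusted p = 0.0716 with only the groups compared in the fit) and RAV2 by -3.11 ± 0.53. GRXS13 changed by -2.70 ± 0.77, adjusted p = 0.0228 (DESeq2 0.0508), with an adjusted p of 0.0931 without T8L replicate 2, 0.0691 without T8L replicate 3, 0.127 without T8H replicate 1 and 0.111 without T8H replicate 2.

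Of 27 flavonoid genes measured at 8 h, 20 rose, 1 fell (MYBL2) and 6 did not pass (22 and 1 adjusted over the list alone). Flavonoid genes had a median log2 change of 3.29 (camera adjusted p = 3.51e-24, or 0.0327 with an estimated correlation). MYBL2, a repressor of anthocyanin synthesis, was the member that fell (-1.23 ± 0.26). Of 22 light-signalling genes measured at 8 h, 7 rose, 2 fell (PHYA and CRY2) and 13 did not pass (10 and 2 adjusted over the list alone). Light-signalling genes had a median log2 change of 0.43 (camera adjusted p = 0.00151, or 0.0327 with an estimated correlation). PHYA and CRY2 did not pass without any 1 of the 6 libraries (adjusted p up to 0.176 and 0.172 without T8H replicate 1), nor with no filter (0.116 and 0.127), and PHYA had 0.0622 with the ribosomal RNA covariate. HY5 rose from 2.91 to 14.4 CPM and its relative HYH by 1.83 ± 0.29. Of 20 antenna genes measured at 8 h, 2 rose (LHCA6 and LHCB4.3), 17 fell and 1 did not pass (as many adjusted over the list alone). Antenna genes had a median log2 change of -1.21 (camera adjusted p = 4.34e-15, or 0.119 with an estimated correlation). LHCB2.1 changed by -2.0 ± 0.26, LHCB4.2 by -2.09 ± 0.28 and LHCA6 by 0.78 ± 0.18. At 8 h LHCB4.3 had an adjusted p of 0.0594 without T8L replicate 1, 0.0793 without T8L replicate 2, 0.124 without T8L replicate 3, 0.0803 without T8H replicate 1 and 0.0593 without T8H replicate 2. Of 22 nuclear photosystem genes measured at 8 h, 10 fell and 12 did not pass (17 adjusted over the list alone). Nuclear photosystem genes had a median log2 change of -0.65 (camera adjusted p = 4.04e-07, or 0.263 with an estimated correlation). PSBQ2 fell from 629 to 297 CPM. The mean ribosomal RNA share was 23% in T8H and 5.38% in T8L.

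Of 18 defence genes measured at 8 h, 7 fell and 11 did not pass (1 and 8 adjusted over the list alone). Defence genes had a median log2 change of -0.69 (camera adjusted p = 0.00013, or 0.219 with an estimated correlation). PAD4 (AT3G52430, chromosome 3, 19431095 to 19434450), an immune regulator gene, fell from 103 to 28.6 CPM (-1.85 ± 0.20, adjusted p = 3.22e-06), and the pathogenesis-related gene PR1 from 392 to 88.6 CPM (-2.15 ± 0.44, adjusted p = 0.00298, or 0.0665 with only the groups compared in the fit). ICS1, of salicylate synthesis, fell from 84.9 to 20.9 CPM. Of 24 stress factor genes measured at 8 h, 10 fell and 14 did not pass (1 and 11 adjusted over the list alone). Stress factor genes had a median log2 change of -0.92 (camera adjusted p = 1.63e-05, or 0.0721 with an estimated correlation). TCH3, a calmodulin-like gene, fell from 299 to 65.4 CPM (-2.20 ± 0.32, adjusted p = 7.24e-05). Of 20 proteasome genes measured at 8 h, 12 fell and 8 did not pass (13 adjusted over the list alone). Proteasome genes had a median log2 change of -0.55 (camera adjusted p = 6.15e-07, or 0.119 with an estimated correlation). PBF1 changed by -0.82 ± 0.17. Of 11 reticulum chaperone genes measured at 8 h, 5 fell (BIP3, CRT1B, PDIL1-1, PDIL2-1 and BZIP60) and 6 did not pass (7 adjusted over the list alone). Reticulum chaperone genes had a median log2 change of -0.69 (camera adjusted p = 0.000295, or 0.263 with an estimated correlation). PDIL1-1 fell from 245 to 123 CPM. PAD4 stood at 34.7 to 40.3 CPM in T0D, and PR1 (4.45) and PDIL1-1 (2.97) rose from T0D to T8L. For these genes T8H lacked part of the rise in T8L. Without T8H replicate 1 CRT1B (0.0926), PDIL2-1 (0.0967) and BZIP60 (0.174) did not pass. Of 20 starvation genes measured at 8 h, 9 fell and 11 did not pass (1 and 12 adjusted over the list alone). Starvation genes had a median log2 change of -1.15 (camera adjusted p = 2.26e-05, or 0.0721 with an estimated correlation). SEN1 changed by -3.48 ± 0.71.

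Of 21 starch and sugar genes measured at 8 h, 7 rose and 14 did not pass (8 adjusted over the list alone). Starch and sugar genes had a median log2 change of 0.44 (camera adjusted p = 4.72e-05, or 0.119 with an estimated correlation). BAM5, a beta-amylase gene, rose from 14.9 to 211 CPM (3.82 ± 0.68, adjusted p = 0.00153). Of 22 photoprotection genes measured at 8 h, 6 rose and 16 did not pass (7 adjusted over the list alone). Photoprotection genes had a median log2 change of 0.41 (camera adjusted p = 0.000532, or 0.119 with an estimated correlation). BCH1 rose by 1.32 ± 0.22. Of 17 photorespiration genes measured at 8 h, 8 rose and 9 did not pass (as many adjusted over the list alone). Photorespiration genes had a median log2 change of 0.50 (camera adjusted p = 0.000295, or 0.263 with an estimated correlation). HPR1 rose by 0.79 ± 0.19. Of 21 Calvin-Benson cycle genes measured at 8 h, 5 rose (RBCS2B, SBPASE, FBA1, CP12-1 and EMB3119) and 16 did not pass (8 adjusted over the list alone). Calvin-Benson cycle genes had a median log2 change of 0.41 (camera adjusted p = 0.000814, or 0.454 with an estimated correlation). CP12-1 rose from 105 to 307 CPM. RBCS2B (0.104) and SBPASE (0.107) did not pass without T8L replicate 3, nor FBA1 (0.124) without T8L replicate 2. Of 53 ribosomal protein genes measured at 8 h, 16 rose and 37 did not pass (21 and 1 adjusted over the list alone). Ribosomal protein genes had a median log2 change of 0.40 (camera adjusted p = 4.04e-07, or 0.219 with an estimated correlation). FTSH5, a thylakoid protease gene, rose from 205 to 437 CPM, while the catalase gene CAT3 fell from 1530 to 658 CPM.

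At 8 h camera gave adjusted p = 0.313 for antioxidant enzymes, 0.637 for chloroplast proteases, 0.518 for chloroplast-encoded photosynthesis genes and 0.0731 for chloroplast gene expression. It gave 0.92 for thiamine synthesis, 0.507 for the clock and 0.518 for cold genes. Heat shock genes had a median of -0.22 and a mean of -0.02 with the test pointing up (adjusted p = 0.897), and chlorophyll synthesis genes a median of 0.14 and a mean of -0.03 (adjusted p = 0.55). LHCB2.4 fell at 8 h from 19.5 to 4.47 CPM (-2.11 ± 0.32, adjusted p = 9.07e-05). ELIP1 rose by 3.34 ± 0.92, adjusted p = 0.0223, with an adjusted p of 0.0868 without T8L replicate 1, 0.073 without T8L replicate 2, 0.0619 without T8L replicate 3 and 0.192 without T8H replicate 1. PAP1, an anthocyanin regulator gene, rose by 2.61 ± 0.62, adjusted p = 0.00882, with an adjusted p of 0.0522 without T8L replicate 2 and 0.0532 without T8H replicate 1. THI1 rose by 0.72 ± 0.22, adjusted p = 0.0239, with an adjusted p of 0.118 without T8L replicate 2, 0.121 without T8L replicate 3 and 0.0717 without T8H replicate 1. ELIP2, HSP101, GPT2, RCA, CCA1, ASN1 and PSBA did not pass, with adjusted p = 0.281, 0.242, 0.841, 0.0841, 0.782, 0.0546 and 0.389.

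At 8 h 1529 genes rose and 1496 fell, 772 and 704 of them by at least 2-fold. The 3025 calls became 1665 without T8L replicate 2, 1933 without T8L replicate 3, 1668 without T8H replicate 1 and 1747 without T8H replicate 2. Camera called 14 lists, and up to 16 for other splits of these 6 libraries.

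**Figure D4:**
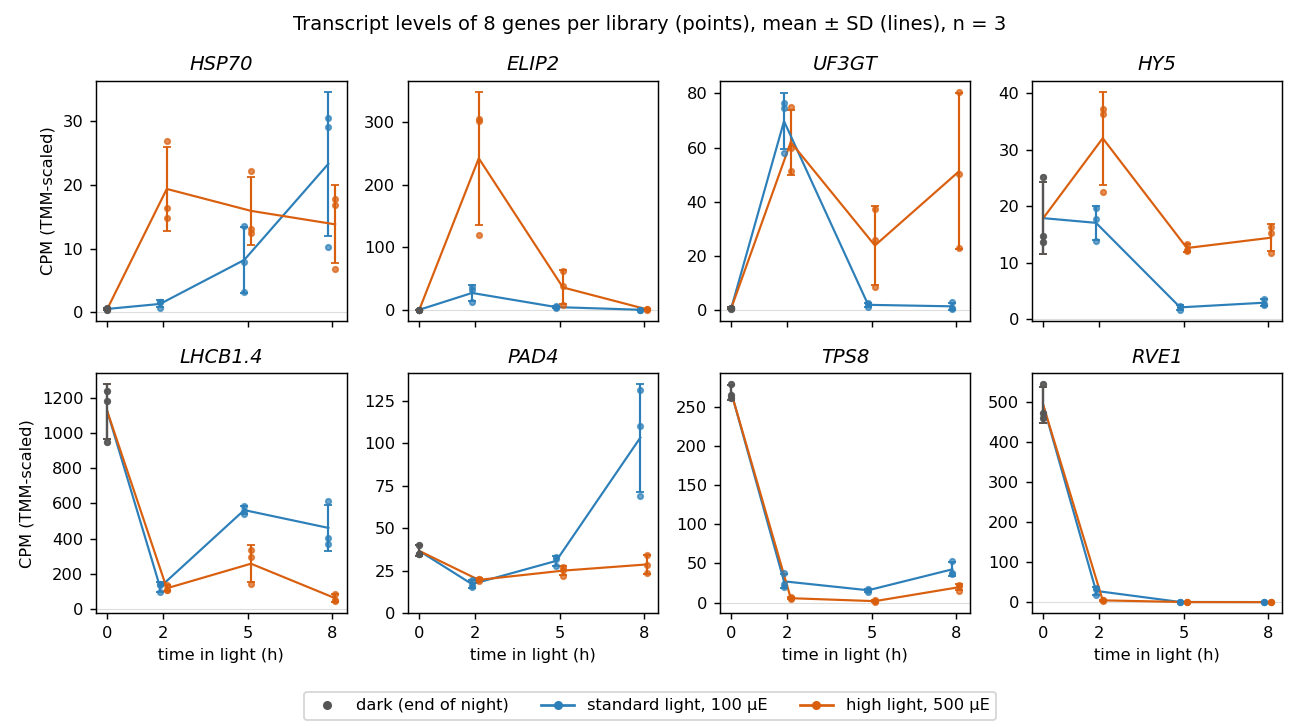
Level of HSP70, ELIP2, UF3GT, HY5, LHCB1.4, PAD4, TPS8 and RVE1 in each library (points, CPM on a linear axis) with the group mean ± SD (n = 3) in dark, standard light and high light. LHCB1.4 at 8 h lies at 461 ± 132 CPM in standard light and 61.8 ± 23 CPM in high light.

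The comparisons of high with standard light at the 3 times use different libraries. Genes are not independent replicates, so the exact p-values do not measure spread between samples. Of the genes that rose, 131 were shared by 2 and 5 h (20.7 expected from independent lists, Fisher's exact p = 6.05e-73). The 5 and 8 h comparisons shared 577 (111 expected, exact p = 3.33e-293), and 2 and 8 h shared 71 (22.1 expected, exact p = 4.43e-19). Of those that fell, 79 were shared by 2 and 5 h (exact p = 3.19e-45), 248 by 5 and 8 h (exact p = 5.24e-74) and 33 by 2 and 8 h (exact p = 0.000649). A total of 37 genes fell at 2 h and rose at 8 h (18.6 expected, exact p = 4.54e-05), and 24 rose at 2 h and fell at 8 h (21.6 expected, exact p = 0.329). From 5 to 8 h 26 genes that rose then fell (109 expected) and 3 that fell then rose (72.5 expected). From 2 to 5 h these counts were 0 and 3. At all 3 times 50 genes rose, among them BCH1, SPPA and RPSAb, and 23 fell, among them TPS8, RAV2, IGMT3 and PORB. The 50 and 23 became 13 and 8 without T2L replicate 1, 18 and 14 with the ribosomal RNA covariate, and 16 and 4 with only the groups compared in each fit. They became 115 and 73 with no filter, 91 and 49 with DESeq2, and 1 and 1 with glmTreat. PORB had an adjusted p of 0.083 at 2 h without T2L replicate 1 and 0.161 at 8 h without T8H replicate 2, and RAV2 0.108 at 2 h without T2L replicate 1.

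Averaged over the 3 times, high light raised ELIP1 (log2 fold change 3.15 ± 0.42, adjusted p = 9.34e-05), CSLA01 (2.89 ± 0.43), UF3GT (2.84 ± 0.33) and KTI1 (2.65 ± 0.45). ELIP2 rose by 2.84 ± 0.52, adjusted p = 0.00107, with an adjusted p of 0.0666 without T8H replicate 1. High light lowered BBX17 (-2.76 ± 0.42), RAV2 (-2.40 ± 0.30), TPS8 (-2.22 ± 0.20), BBX27 (-2.20 ± 0.37) and IGMT3 (-1.80 ± 0.28). Of 27 flavonoid genes measured, 24 rose, 1 fell (MYBL2) and 2 did not pass (25 and 1 adjusted over the list alone). Flavonoid genes had a median log2 change of 1.99 (camera adjusted p = 2.47e-27, or 0.0166 with an estimated correlation). Of 53 ribosomal protein genes measured, 34 rose and 19 did not pass (38 adjusted over the list alone). Ribosomal protein genes had a median log2 change of 0.38 (camera adjusted p = 1e-12, or 0.113 with an estimated correlation). In total 2348 genes rose and 1945 fell. The 4293 calls became 1883 when the mean was taken over 2 and 8 h alone. Camera called 14 lists, and up to 14 for other label swaps within times.

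The difference of the high-light effect between 8 h and 2 h was tested directly. It was positive for DFR (log2 fold change 5.40 ± 0.77, adjusted p = 0.000523), UF3GT (5.32 ± 0.79), TT7 (4.58 ± 0.96) and EMB3120 (5.74 ± 0.99). GRP23 had 5.09 ± 1.21, adjusted p = 0.0158, with an adjusted p of 0.0512 without T2H replicate 1. DFR stood at 200 ± 38.6 CPM in T2L and 121 ± 28.8 in T2H, and at 2.63 ± 1.81 in T8L and 67.7 ± 47.4 in T8H. The difference was negative for KTI1 (-5.02 ± 1.13), UGT76B1 (-4.87 ± 0.89), HSP70 (-4.70 ± 0.74) and ARD3 (-4.40 ± 0.48). With limma voom the adjusted p was 0.0521 for KTI1 and 0.158 for UGT76B1. Of 20 antenna genes measured, 1 was positive (LHCA6), 17 were negative and 2 did not pass (as many adjusted over the list alone). Antenna genes had a median log2 change of -1.49 (camera adjusted p = 2.94e-13, or 0.173 with an estimated correlation). Of 23 heat shock genes measured, 1 was positive (CPHSC70-1), 7 were negative and 15 did not pass (as many adjusted over the list alone). Heat shock genes had a median log2 change of -1.20 (camera adjusted p = 0.000402, or 0.232 with an estimated correlation). In total 995 genes had a positive and 1008 a negative difference. The 2003 calls became 1096 without T8L replicate 2, 1262 without T8L replicate 3, 1153 without T2H replicate 1, 1249 without T8H replicate 1 and 1167 without T8H replicate 2. With the ribosomal RNA share as covariate they became 971, of which 60.6% were positive.

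Standard light was compared with the end of the night to follow the course of the day. SEN1 (AT4G35770, chromosome 4, 16944878 to 16946266), a dark-induced gene, fell from 878 ± 120 to 0.355 ± 0.244 CPM at 2 h (log2 fold change -11.19 ± 0.66, adjusted p = 1.15e-10). The raffinose synthase gene DIN10 fell from 1960 to 5.29 CPM, ASN1 from 1210 to 2.51 CPM and the scaffold gene BT2 from 779 to 1.4 CPM. GAT1_2.1, a glutamine amidotransferase gene with 753 counts in the dark, held none in T2L, at least 61.1-fold lower (DESeq2 adjusted p = 0.137). XTH31, for a xyloglucan hydrolase, rose from 0.237 to 28.9 CPM (6.89 ± 0.65, adjusted p = 1e-07). TT19, for an anthocyanin carrier, rose from 0.781 to 76.1 CPM, UF3GT from 0.736 to 69.7 CPM and ELIP2 from 0.143 to 27.1 CPM. TBL26 held 2 counts in the dark and 30.6 CPM in T2L, a ratio of 637 (176 to 5260).

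RVE1 fell from 492 to 0.712 CPM at 5 h of standard light (-9.41 ± 0.40, adjusted p = 7.25e-15), and ERD5, for proline dehydrogenase, from 1070 to 0.959 CPM. CCA1 (AT2G46830, chromosome 2, 19245591 to 19248915), a clock gene of the morning, fell from 560 ± 81.6 to 0.907 ± 0.326 CPM at 8 h (-9.24 ± 0.36, adjusted p = 1.45e-15), its partner LHY from 446 to 0.515 CPM and COL2 from 332 to 0.445 CPM. FKF1 held 2 counts in the dark and 68.6 CPM in T5L, a ratio of 1460 (405 to 12100). The evening gene ELF4, with none in the dark, stood at 12 CPM in T8L, at least 56.1-fold higher. At 5 h COR15B, a cold-response gene, rose from 3.34 to 375 CPM, and IGMT5 by 7.61 ± 0.86. By 8 h UGT76B1 rose from 0.141 to 34.1 CPM (7.82 ± 0.78, adjusted p = 3.43e-08).

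Of 20 starvation genes measured at 2 h of standard light, 1 rose (D2HGDH), 17 fell and 2 did not pass (as many adjusted over the list alone). Starvation genes had a median log2 change of -3.81 (camera adjusted p = 5.42e-31, or 0.000118 with an estimated correlation). D2HGDH (0.65) had an adjusted p of 0.146 with the ribosomal RNA covariate, 0.0557 with only the groups compared in the fit and up to 0.126 without 1 library (T0D replicate 3). The starvation median was -4.10 at 5 h and -2.76 at 8 h. Of 21 starch and sugar genes measured at 5 h of standard light, 16 rose, 3 fell (GBSS1, BAM1 and BAM9) and 2 did not pass (as many adjusted over the list alone). Starch and sugar genes had a median log2 change of 2.68 (camera adjusted p = 2.85e-12, or 0.00906 with an estimated correlation). PHS2, for a glucan phosphorylase, changed by 5.84 ± 0.24. In standard light 4136 genes rose and 4195 fell at 2 h, 4495 and 4665 at 5 h, and 4143 and 4268 at 8 h. Camera called 8, 8 and 14 lists, and up to 9, 11 and 15 for other splits of the same libraries.

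High light was compared with the dark to give the whole change from night to strong light. ELIP2 rose from 0.143 ± 0.14 to 243 ± 106 CPM at 2 h (log2 fold change 10.65 ± 1.02, adjusted p = 4.36e-07) and ELIP1 from 1.08 ± 0.857 to 256 ± 89.8 CPM (7.89 ± 0.82, adjusted p = 1.06e-06). MIOX2 (AT2G19800, chromosome 2, 8530865 to 8533779), for an inositol oxygenase, fell from 208 CPM to no counts in T2H, at least 968-fold lower. UGT84A1, a sinapate glucosyltransferase gene with none in the dark, stood at 13.1 CPM in T2H, at least 61.6-fold higher. TBL26 stood at 60.7 CPM, a ratio of 1300 (359 to 10700), and CYP707A2, of abscisic acid breakdown, at 19.2 CPM, a ratio of 271 (92.3 to 1320). SEN1 changed by -9.78 ± 0.59, BT2 by -9.27 ± 0.38 and DIN10 by -8.91 ± 0.55. GAT1_2.1 held no counts, at least 82.6-fold lower, but did not pass with DESeq2. At 5 h CBF3, with none in the dark, stood at 24.1 CPM, at least 113-fold higher. XTH31 changed by 8.37 ± 0.65, RVE1 by -10.30 ± 0.43 and GDPD2 by -9.59 ± 0.38. At 8 h ELF4 stood at 35.4 CPM, at least 166-fold higher. PRR3, a clock regulator gene, rose from 0.267 to 55.7 CPM and BAM5 from 1.17 to 211 CPM. LHY changed by -10.10 ± 0.37 and ASN1 by -9.74 ± 0.61.

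Of 20 starvation genes measured at 5 h of high light, 18 fell and 2 did not pass (as many adjusted over the list alone). Starvation genes had a median log2 change of -4.91 (camera adjusted p = 2.68e-30, or 0.000164 with an estimated correlation). The starvation median was -4.57 at 2 h and -3.92 at 8 h. Of 21 starch and sugar genes measured at 5 h of high light, 16 rose, 2 fell (BAM1 and BAM9) and 3 did not pass (17 and 2 adjusted over the list alone). Starch and sugar genes had a median log2 change of 2.59 (camera adjusted p = 1.95e-13, or 0.00777 with an estimated correlation). DPE2, for a glucanotransferase of starch breakdown, changed by 4.29 ± 0.19. In high light 4279 genes rose and 4214 fell at 2 h, 4777 and 4483 at 5 h, and 4593 and 4682 at 8 h. Camera called 11, 10 and 9 lists, and up to 13, 12 and 10 for other splits of the same libraries. All comparisons with the dark share the 3 T0D libraries, so they are not set against each other.

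The authors' deposited table called 24, 307 and 603 genes between high and standard light at 2, 5 and 8 h. Of its genes, 100% were also called here in each of its 9 comparisons, with the same sign. The log2 fold changes here differed from its own by a median of 0.001 to 0.031. With a minimum fold of 1.5, glmTreat called 24, 294 and 587 genes here, of which 24, 291 and 582 were in that table.

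Markers of other tissues were measured to see whether the groups differed in them. Of the root markers, NRT2.1 and PHT1;4 had group means of 0.239 to 3.63 CPM. The flower marker AG had 0.0984 to 0.888 CPM, and seed markers were below the filter. No measured guard cell or dividing cell marker passed in edgeR between high and standard light. The epidermal genes PDF1 (log2 fold change 1.80, adjusted p = 0.0262) and GL2 (log2 fold change 1.17, adjusted p = 0.0462) were higher in high light at 5 h, as was SAG13 of senescing leaf (log2 fold change 1.97, adjusted p = 0.0323). ATML1 (log2 fold change 0.02, adjusted p = 0.956) and GL1 (log2 fold change 0.50, adjusted p = 0.717) of the epidermis and SAG29 (log2 fold change 2.50, adjusted p = 0.0807) of senescing leaf did not pass at 5 h, and GL2 had -1.01 at 8 h (adjusted p = 0.0949). The phloem gene SUC2 was lower at 8 h (log2 fold change -0.81, adjusted p = 0.0215), while SWEET12 (-0.53, adjusted p = 0.442), XCP1 and IRX3 of the veins did not pass. The flower gene PI held no counts in T2H, at least 4.56-fold lower than in T2L (adjusted p = 0.0423). SAG12 had 14.5 ± 13.6 CPM in T2H and 0.505 ± 0.875 in T2L without passing (adjusted p = 0.206).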

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

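Of the tests in this part, the shares of chloroplast genes below 0 were chosen only after the result was seen, and those with the ribosomal RNA share or limma voom after the data were seen. The effect of high light differed between 8 h and 2 h in 2003 genes by a test of the difference itself (edgeR, adjusted p under 0.05). The count was 1096 to 2391 without each library in turn. Camera called 13 lists for this difference, and with an estimated correlation 0, with 6 at an unadjusted p under 0.05. The median log2 difference was positive for chloroplast-encoded photosynthesis genes (0.54), chloroplast-encoded gene expression genes (1.07), photorespiration genes (0.28), flavonoid genes (3.13), starch and sugar genes (0.57) and light-signalling genes (0.51). Photorespiration genes had an adjusted p of 0.0805 without T2L replicate 3, and with the ribosomal RNA share as covariate those of chloroplast-encoded photosynthesis and reticulum chaperone genes were 0.381 and 0.105. The median difference was negative for stress factor genes (-1.0), heat shock genes (-1.20), antenna genes (-1.49), nuclear photosystem genes (-1.12), reticulum chaperone genes (-0.85), proteasome genes (-0.74) and defence genes (-1.22).

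Among named genes the log2 difference was positive for DFR (5.40), UF3GT (5.32), TT7 (4.58), LDOX (4.45), CSLA01 (3.57), F3H (3.56), NEET (3.46), TT4 (3.35), BAM5 (3.28), MYB111 (3.13), ERF2 (2.61) and CP12-1 (1.95). Positive differences were also found for IGMT4 (1.85), RUP2 (1.82), RPOB (1.69), HYH (1.41), HY5 (1.41), LHCA6 (1.16), THI1 (1.11) and HPR1 (0.83). Negative differences were found for GPX1 (-0.81), FTSH8 (-0.98), PSBQ2 (-1.05), APX1 (-1.47), LHCB2.4 (-1.58), ZAT12 (-1.65), ZAT10 (-1.70), CAT3 (-1.85), LHCB4.2 (-1.86) and HSP101 (-2.01). They were also found for PAD4 (-2.06), ICS1 (-2.12), LHCB2.1 (-2.14), TCH3 (-2.20), FER1 (-2.40), GOLS2 (-2.57), LHCB1.4 (-2.82), BCB (-2.96), 4CL5 (-3.35) and PR1 (-3.53). Further genes with a negative difference were Hsp70-2 (-3.69), HSP90.1 (-3.81), ARD3 (-4.40), HSP70 (-4.70), UGT76B1 (-4.87), SEN1 (-4.88), HSFA2 (-4.95) and KTI1 (-5.02). Of these 48 genes, 11 had an adjusted p of 0.05 or more without some library (group and replicate number given), namely BAM5 (without T2H 2 0.0535, T2H 3 0.0608, T2L 1 0.0734, T8H 1 0.0793, T8H 2 0.0516, T8L 1 0.0679, T8L 2 0.0858), CSLA01 (without T2H 2 0.0653, T2H 3 0.0622, T2L 1 0.0602, T2L 2 0.0661, T2L 3 0.0511, T8H 1 0.0784, T8H 2 0.0869, T8L 1 0.0862, T8L 2 0.105), FTSH8 (without T2H 1 0.0684, T2L 1 0.054, T8H 1 0.055, T8L 3 0.0556) and GOLS2 (without T2H 1 0.0891, T2L 1 0.0695, T2L 3 0.0616, T8H 2 0.0761, T8H 3 0.0614, T8L 1 0.0703). The others were GPX1 (without T2H 1 0.157, T2H 3 0.0856, T2L 1 0.0802, T2L 2 0.107, T2L 3 0.054, T8H 1 0.115, T8H 2 0.106, T8H 3 0.0827, T8L 1 0.117, T8L 2 0.076, T8L 3 0.0585), HPR1 (without T2H 1 0.122, T2H 3 0.0751, T2L 1 0.0669, T2L 3 0.066, T8H 1 0.065, T8H 2 0.0756, T8H 3 0.07, T8L 2 0.119, T8L 3 0.108), LHCB2.4 (without T2L 1 0.0528, T2L 2 0.0523, T8H 2 0.0686, T8L 1 0.0643), PSBQ2 (without T2L 1 0.0544, T2L 2 0.0589, T8H 1 0.0504, T8H 2 0.0691), RUP2 (without T2L 2 0.0574, T8H 1 0.0749, T8L 3 0.0581), THI1 (without T2H 1 0.0602, T8L 2 0.0706, T8L 3 0.0692) and ZAT12 (without T2H 1 0.107, T2L 3 0.0537, T8H 2 0.0668, T8L 2 0.086). With the ribosomal RNA share as covariate 13 of the 48 did not pass, namely CSLA01, BAM5, ERF2, HYH, HY5, GPX1, FTSH8, LHCB2.4, ZAT12, ZAT10, CAT3, HSP101 and GOLS2, and with limma voom 5, ERF2, GOLS2, 4CL5, UGT76B1 and KTI1.

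Camera called chloroplast-encoded gene expression genes lower in high light at 2 and 5 h, where 4 and 10 of 26 passed, but not with an estimated correlation (adjusted p = 0.275 and 0.244). Their mean log2 level differed by -0.93 ± 0.25 at 5 h, and by -0.69 ± 0.17 after adjustment for the ribosomal RNA share, which argues against that share as the whole cause at 5 h. At 2 h the difference went from -0.85 ± 0.25 to -0.45 ± 0.18 with the same adjustment. A lower yield of all chloroplast RNA at 5 h may account for it, since 86.1% of the 79 chloroplast protein-coding genes tested lay below 0, a share between the bounds set for and against it. That explanation and a response to the light stay open.

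Camera called heat shock genes higher in high light at 2 h, where 6 of 23 passed, but not with an estimated correlation (adjusted p = 0.188). Without each of the 6 libraries in turn their median log2 change was at lowest 0.57 (T2H replicate 2), so no single library carried it. With the ribosomal RNA share as covariate the median was 0.84 (camera adjusted p = 4.25e-06), which argues against that share as its whole cause. Of the 6 calls 2 were kept with it. The fold went from 1.46 ± 0.29 to 0.92 ± 0.23 for HSC70-1 and from 1.42 ± 0.35 to 1.05 ± 0.38 for HSP101, and with little loss from 2.61 ± 0.51 to 2.45 ± 0.61 for HSP90.1 and from 1.79 ± 0.36 to 1.53 ± 0.41 for ROF2, where the SE grew. The rise may be a response to the light, a hypothesis found and tested on the same data. Warmth from the nearer lamp was not ruled out.

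With 3 libraries against 3, the 10 splits are too few for a share under 0.05. High against standard light at 2, 5 and 8 h called 523, 2361 and 3025 genes, and the highest of the other splits 1, 2 and 0. Standard light against dark called 8331, 9160 and 8411, and the highest others 3, 0 and 1. High light against dark called 8493, 9260 and 9275, and the highest others 12, 3 and 0. For lists the highest other split exceeded the real one in each comparison. Over 50 label swaps within times, 1 gave as many as 4293 genes for the mean effect, the real one, with 246 as the highest other. For the difference, 1 gave as many as 2003, the real one, with 1199 as the highest other. Swaps that mix differing groups raise the spread, so neither gene count excludes chance. Nor do the lists. Of the 50 swaps, 5 called as many as 14 for the mean and 7 as many as 13 for the difference. The highest other was 14 in both.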

How the results depend on the processing

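Of the tests in this part, those with the ribosomal RNA covariate, with limma voom, without both libraries that stand apart and of the mean over 2 and 8 h were chosen only after the data were seen. Of 1113 calls for named genes, 2 were lost with RLE size factors, 40 with no filter, 97 with the ribosomal RNA covariate, 55 with limma voom and 343 with glmTreat, and none of these 5 settings turned the direction of a called gene. DESeq2 lost 6 of 1112, the groups compared alone in the fit 93 of 1105, nuclear genes alone 2 of 1022, both libraries left out 30 of 567, and the stricter filter 0 of 1089. For values that moved, the cause was not tested unless stated. Depth allows no fold below the floor of 3 counts.

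With no filter, under which more genes were tested, high against standard light at 2 h gave 1336 genes, and with DESeq2 1078. The ribosomal RNA covariate gave 164 genes at 2 h and 971 for the difference of 8 h and 2 h. It turned 3 values of genes that had not passed, RCA at 2 h (-0.23), PSBA at 2 h (0.31) and HSP101 at 5 h (-0.04). Leaving out both libraries gave 5089 genes at 5 h, with 49.3% of them higher against 60.6% of the 2361. Limma voom gave 4557 genes at 5 h, 7624 at 8 h and 3755 for the difference, with PSBA at 2 h at 0.08 and CCA1 at 5 h at -0.06. The groups compared alone in the fit gave 163, 718 and 6455 genes at 2, 5 and 8 h. The mean over 2 and 8 h gave 1883 genes, and 32 of 103 calls were lost. In it 2 called genes turned without passing, ZAT10 from 0.57 (adjusted p = 0.0184) to -0.12 and BIP2 from 0.47 (adjusted p = 0.0405) to -0.02. A minimum fold of 1.5 in glmTreat, which asks for more than a difference from 0, gave 24, 294 and 587 genes for high against standard light, 4805, 5905 and 5012 for standard light against dark, 5181 and 5994 for high light against dark at 2 and 8 h, 588 for the difference, and 291 for the mean, 68.7% of them higher against 54.7%. With an estimated correlation camera called 0, 3 and 2 lists for high against standard light, 1, 3 and 2 for standard light against dark, 1, 2 and 3 for high light against dark, 3 for the mean and 0 for the difference. The 0 at 2 h and for the difference stand beside 3 and 6 lists at an unadjusted p under 0.05.

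Leaving out each library in turn gave 110 to 791 genes at 2 h, 847 to 4678 at 5 h, 1665 to 2610 at 8 h and 1096 to 2391 for the difference. The direction of genes that had not passed turned in 9 fits. PSBA at 2 h ranged from -0.38 to 0.27, ASN1 at 2 h from -0.15 to 1.11, HSP101 at 5 h from -0.01 to 0.42, CCA1 at 5 h from -0.01 to 0.29, GPT2 at 8 h from -0.66 to 0.26 and CCA1 at 8 h from -1.51 to 0.11. PSBA stood at 0.27 without T2L replicate 3 and 0.13 without T2H replicate 2, GPT2 at 0.26 without T8L replicate 2 and 0.06 without T8H replicate 2, and CCA1 at 8 h at 0.11 without T8L replicate 3 and 0.10 without T8H replicate 3. ASN1 turned without T2H replicate 1, HSP101 without T5H replicate 2 and CCA1 at 5 h without T5H replicate 1. Over protein-coding loci alone the chloroplast share was 51% ± 0.716 in T8L, 32.9% ± 12.9 in T5H and 46.9% ± 1.19 in T8H. Over all loci it was 48.7%, 28.7% and 36.8%.

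The replicate block, fitted with the replicate number as a term, lost 23 of 1113 calls for named genes and called the same number of lists as without it except 10 in place of 9 for high light against dark at 8 h. As a check of pairing, the deviations of 63 same-numbered pairs from their group means had a median correlation of 0.002 (-0.144 to 0.33). Only 2 of the 63 were over 0.1, and 5 of 21 libraries correlated best with a library of their own number, so the numbers do not pair the samples.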

Other observations

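Of the tests in this part, the slope on the standard light time course and the slope of the clock genes were chosen only after the result was seen, and those with the ribosomal RNA share or limma voom after the data were seen. The first 4 principal components held 30.9%, 19.1%, 11.5% and 6.4% of the variance. The median SD of log2 CPM was 0.441 in T5H and 0.199 in T8L, and the sample quality weights of limma voom ran from 0.239 for T5H replicate 1 to 2.91 for T8L replicate 2.

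On the first component T8H (35.6 to 49.6) stood by T5L (34.5 to 44.1) and not T8L (6.3 to 8.6), and on the second (31.4 to 52.6) between T5L (13.9 to 24.8) and T8L (81.5 to 89.1). On the third and the fourth it stood nearer to T8L, with -20.1 to -14 on the fourth against -33.5 to -13.5 in T8L and 43.6 to 49 in T5L. The slope of the 8 h high-light effect on the standard light change from 5 to 8 h was taken over 19401 nuclear genes. It was -0.40, -0.33 and -0.35 for 3 choices of the library held out (median -0.35). Each side held other T8L libraries, but a trait of the T8L group would also make it negative. Adjusted for the ribosomal RNA share the median slope was -0.34, but T8L and T8H shares did not overlap, so that cause stays open. For 20 clock genes the median slope was 0.04, without an SE. It bears on a delay only, so a clock shift stays open. A slower daily course in high light may account for the negative slope, a hypothesis found and tested on the same data. Genes are not independent replicates.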
